A study of Mus musculus with 25 samples.

How the data were processed

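Polysomal RNA from kidney podocytes of Col1a1-eGFPL10a mice was measured on 25 arrays, per the labels after ribosome purification, 1 round of NuGEN WT-Ovation amplification and biotin labelling with the Encore module. The array is an Affymetrix mouse design with perfect-match probes only, per the platform line of the probe table. The deposited values are 1 log2 value per probe set and array. The log2 base is read from the values, which ran from 1.86 to 13.62: a natural log would put the highest intensity at 820000, above the 16-bit limit of 65535. How the authors summarized and normalized the probe sets is not given in the sources used here; the medians of the 25 arrays differed by at most 0.17, so the values had been scaled to each other. Depth has no counterpart on an array beyond the signal, and the number of arrays limits the precision. The labels name the ages both as 2, 5 and 44 weeks and by stage, and the weeks are used.

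Groups were taken from the titles and source names: 4 WT and 4 KI arrays at 2 weeks, 5 and 4 at 5 weeks, and 4 and 4 at 44 weeks. All columns were used. Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers, 99.3% of which were found. Of 45141 probe sets 28898 had 1 gene symbol, 551 had several, 15692 were not in the annotation used here and 104 were controls. For each of 17097 genes the probe set with the highest mean over all arrays was kept (7180 genes had more than 1), and the 30% of genes with the lowest mean were left out (limit 4.603), which left 11968. Actn4 has no named probe set in that annotation and was not analysed here. Some items are not reported here.

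Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on a model of 6 group means over all arrays, with 19 residual degrees of freedom and 3.05 prior ones. The contrasts were KI against WT at each age and averaged over ages, 5 against 2 and 44 against 5 weeks in WT, and the differences of the genotype effect between ages. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Fold changes are differences of group means on the log2 scale with limma's moderated standard error. Gene lists, 22 in number and at least 5 genes each after filtering, were written before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. At the estimated correlation no list was called in any of the 6 comparisons of groups. A 23rd set, Y-linked genes and Xist, served only to describe sex. Array measures were compared with exact two-sided permutation tests, adjusted over 45 tests. Genes near Actn4 were counted within 20 Mb by Fisher's exact test.

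Genes in the text follow a rule written before the data were examined. It names Actn4, Actn1 and Col1a1 in every genotype comparison, and the 12 largest rises and 12 largest falls that passed with no overlap between arrays (at every age for the average). It adds up to 4 members of each list by p, the 6 largest each way for interactions, and the 5 smallest p each way where none passed; of these the text gives a part. Predicted genes were counted, and the next named gene took their place. In the average the rule names Prodh2; the other genes near Actn4 given there (of which it names Dmpk and Eml2 at 2 weeks) and the group of all myosin heavy chain genes were chosen after their values were seen.

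Simulated data with known changes checked each step over 11968 genes. With 200 changed genes, the share of 2-fold changes recovered was 80.6% for KI against WT at 2 weeks, 77.6% at 5 weeks, 65.7% at 44 weeks and 95.5% for the average. It was 79.1% for WT at 5 against 2 weeks and 80.6% at 44 against 5 weeks. The false share of calls ran from 4.26% to 6.88%. The simulated noise was independent between genes and had the same spread in every group, unlike the real arrays. This share therefore does not carry over to the real calls.

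Alternatives were quantile normalization, centring on array medians, no filter or a 50% filter on dim genes, and the mean of all probe sets of a gene. Others were a trended robust prior, array weights, only the arrays compared, a covariate for the mean of the tubule markers, a sex covariate, each array left out in turn, and other windows around Actn4. Leaving out WT arrays 7, 8 and 9 of 5 weeks and covariates for the actin and the Gapdh 3′ minus 5′ signal were added after the data were seen. A planned offset on the linear scale was not run, since the values were already log2. In the tests of explanations, a limit of 50% of the fold kept was written beforehand (for sex, after its values were seen), and the margin of 1 standard error around it was chosen after the percentages were known. For the smooth muscle explanation the criterion was written for 5 weeks, after the myosin values were seen. An average-over-ages form was tried once both values were known and would have excluded the explanation; the 5-week form was kept for the verdict, and both values are reported. Shared controls were simulated 50 times with unchanged groups and split 20 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).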

Results

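The series asked how podocytes, the cells that wrap the glomerular capillaries, change their translated transcripts when they carry a point mutation in Actn4, which encodes the actin crosslinker alpha-actinin-4. Mice carrying a ribosomal protein L10a fused to a green fluorescent protein behind a collagen 1α1 promoter were crossed with the knock-in line. Ribosomes were then purified from their kidneys (translating ribosome affinity purification, TRAP), and the polysomal RNA was amplified and hybridized to a mouse array. Control (WT) and knock-in (KI) mice were taken at 2, 5 and 44 weeks, with 4 arrays in every group except WT at 5 weeks, which had 5. The 25 arrays held 45141 probe sets each. Whether the KI mice carried 1 or 2 mutant alleles is not given in the sources used here, and the labels do not say that each array came from a separate animal, so p-values measure the spread between these samples. The number of arrays limits the precision: the median standard error of a fold change was 0.17 (log2) at 5 weeks and 0.18 at 2 and at 44 weeks. Actn4 itself was not analysed here, so the genotype labels could not be checked on the targeted gene.

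Podocyte transcripts were abundant in every group, but so were transcripts of other kidney cells. The proximal tubule list averaged 9.90 in WT and 10.41 in KI at 44 weeks. In WT 44-week array 15 it was 10.667, above the podocyte identity list at 10.538. No group of unpurified kidney RNA is among the arrays, so enrichment of podocyte transcripts cannot be judged. The mean of the podocyte identity list was 10.40 ± 0.17 (log2, SD, n = 4) in WT and 10.24 ± 0.07 (n = 4) in KI at 2 weeks, 10.64 ± 0.08 (n = 5) and 10.58 ± 0.08 (n = 4) at 5 weeks, and 10.75 ± 0.15 and 10.57 ± 0.05 (n = 4 each) at 44 weeks. Proximal tubule markers were higher in KI by 0.63 at 2 weeks, 0.72 at 5 weeks and 0.51 at 44 weeks (exact two-sided permutation p = 0.057, 0.016 and 0.17; adjusted over 45 such tests 0.15, 0.08 and 0.27). Endothelial markers were higher in KI by 0.40, 0.76 and 0.37 (exact p = 0.23, 0.016 and 0.17; adjusted 0.36, 0.08 and 0.27). The mean of all tubule markers, used as a covariate in an alternative fit, was higher in KI by 0.53, 0.63 and 0.22 (exact p = 0.057, 0.016 and 0.37; adjusted 0.15, 0.08 and 0.45). None of the 45 comparisons passed after adjustment, and the lowest adjusted p was 0.08. With 4 arrays against 4 the smallest possible exact p was 0.029, and with 4 against 5 it was 0.0079.

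**Figure D1:**
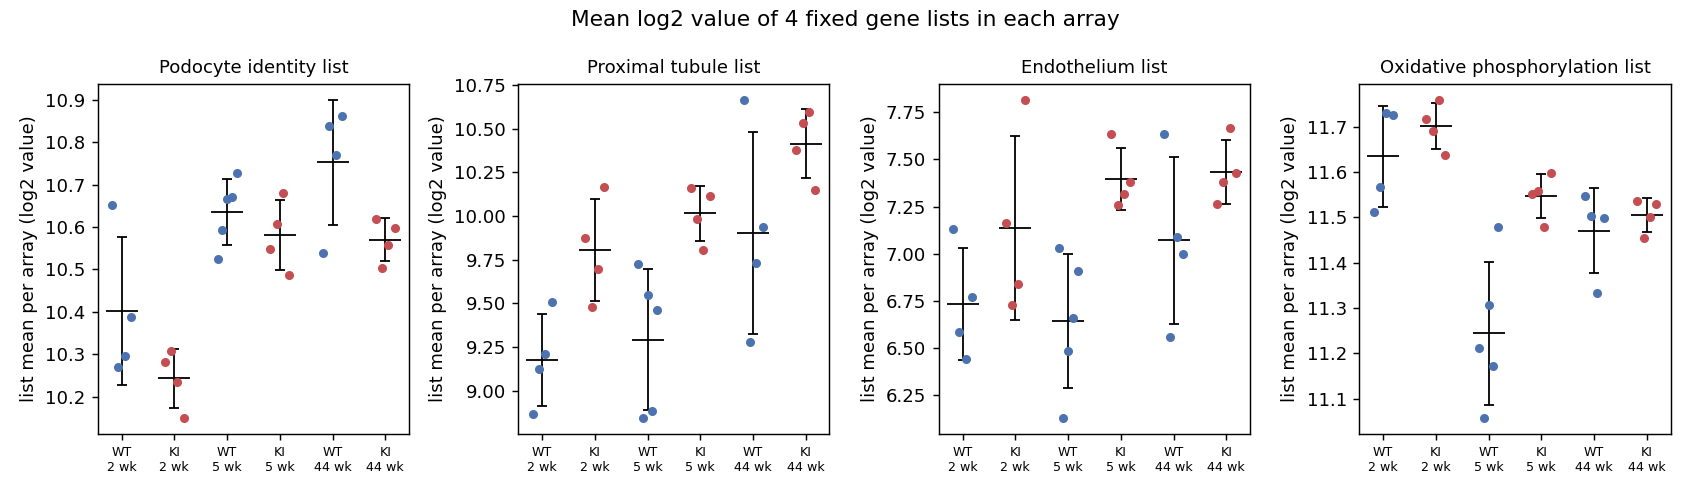
Each point is the mean log2 value of a fixed gene list in an array, by genotype (blue WT, red KI) and age, with the group mean and SD as bars. At 5 weeks the proximal tubule list averaged 9.29 in WT and 10.02 in KI, and the endothelium list 6.64 and 7.40.

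Sex was labelled unknown, and the groups differed in it as measured: arrays with high Y-linked signal numbered 4 of 4 in WT and 1 of 4 in KI at 2 weeks, 2 of 5 and 3 of 4 at 5 weeks, and 1 of 4 and 3 of 4 at 44 weeks. The lowest mean Y-linked value among these arrays was 7.26, against a highest of 3.68 among the others. As measures of RNA integrity, the 3′ minus 5′ signal of the actin control was 1.17 ± 0.15 in KI and 1.52 ± 0.06 in WT at 5 weeks (exact p = 0.0079, adjusted 0.08). That of the Gapdh control went the other way, at 1.48 ± 0.19 and 1.22 ± 0.39 (exact p = 0.24, adjusted 0.36), and at 2 weeks it was 1.21 ± 0.17 in KI and 1.66 ± 0.13 in WT (exact p = 0.029, adjusted 0.12). The 18S ribosomal RNA 5′ signal was 10.30 ± 0.44 in KI and 8.74 ± 0.73 in WT at 5 weeks (exact p = 0.024, adjusted 0.11). The first 3 principal components carried 35.7%, 18.3% and 10.4% of the variance.

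At 5 weeks the KI arrays differed broadly from the WT arrays, by calls that depended on which arrays were used. Many respiratory chain genes and a part of the endothelial, tubule and leukocyte markers rose, as did some myosins and the keratins Krt18 and Krt19. Actin regulators moved both ways, and 6 of 18 slit diaphragm genes and 3 of 26 immediate-early genes fell. Of 11968 genes tested with limma, 2638 passed, 1710 higher and 928 lower in KI; 373 of the higher and 32 of the lower ones differed by more than 2-fold. For 1432 genes (12%) the arrays of the groups did not overlap, against 1.59% by chance, and 1108 of the called genes were among them. The share of higher calls was 64.8% with the values as deposited, 56% after quantile normalization and 49.9% with each array centred on its median. Leaving out single arrays gave 1386 called genes without WT array 7, 1483 without WT 9, 1480 without KI 23 and 4077 without WT 10. Array weights gave 4821. With only the arrays compared, 478 of the 2638 were still called, and without WT arrays 7, 8 and 9 only 1 was.

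Among the largest rises were 4 genes of myosin heavy chains. Myh11, the smooth muscle myosin, rose by 3.09 ± 0.89 (log2 fold change ± SE, limma adjusted p = 0.019), Myo15b by 2.90 ± 0.59 (0.0036), Myo7a by 2.61 ± 0.79 (0.024) and Myo7b by 2.54 ± 0.61 (0.0077), the last being motors of microvilli and stereocilia. Fbxo34, an F-box protein, rose by 3.29 ± 0.89 (0.014), the plakin Evpl by 2.94 ± 0.62 (0.0041), the actin-binding drebrin Dbn1 by 2.77 ± 0.78 (0.017) and the tight junction protein Cgn by 2.26 ± 0.69 (0.026). The actin bundler Lcp1 rose by 2.22 ± 0.76 (0.04), the mitochondrial disaggregase Clpb by 2.20 ± 0.41 (0.0028) and Haao, of tryptophan breakdown, by 2.18 ± 0.40 (0.0026). With the tubule covariate Myo7a, Cgn and Lcp1 turned to -0.01, -0.01 and -0.34.

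The largest falls were smaller. Ccdc73, a coiled-coil protein, changed by -1.53 ± 0.30 (limma adjusted p = 0.0031), the lipid flippase Atp10a by -1.30 ± 0.30 (0.0067), the non-coding Cep83os by -1.27 ± 0.26 (0.0033) and the cyclic AMP phosphodiesterase Pde4b by -1.19 ± 0.17 (0.00058). The adhesion protein Ceacam2 changed by -1.18 ± 0.24, the orphan nuclear receptor Nr2c1 by -1.17 ± 0.20, the intraflagellar transport gene Ttc30a1 by -1.15 ± 0.27, the endosomal sorting nexin Snx16 by -1.09 ± 0.24 and the proteasome lid subunit Psmd11 by -1.05 ± 0.25. Krt222, Tmem80 and Heca changed by -1.04 ± 0.20, -1.03 ± 0.21 and -1.01 ± 0.28. For the rises and falls named here the KI and WT arrays did not overlap. The paralog Actn1 did not pass (0.46 ± 0.23, adjusted p = 0.15), and Col1a1, whose promoter drives the ribosome tag, rose by 1.09 ± 0.39 (0.05 after rounding), a rise that ended and turned to -0.09 without WT arrays 7, 8 and 9.

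**Figure D2:**
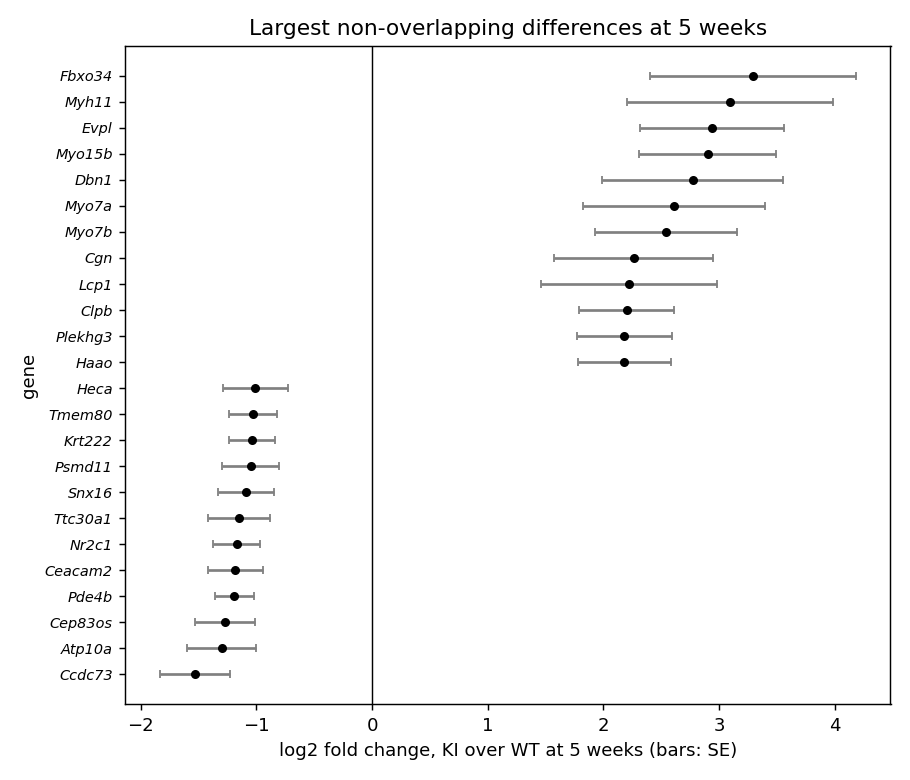
Log2 fold change of KI over WT at 5 weeks (x axis) for the genes with the largest non-overlapping differences, with bars for the SE. The rises reach 3.29 (Fbxo34) and the falls -1.53 (Ccdc73).

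In the slit diaphragm and polarity list at 5 weeks, 1 gene rose, 6 fell and 11 of 18 did not pass. The polarity gene Scrib rose by 0.85 ± 0.21, while the nephrin kinase Fyn (-0.46 ± 0.13), the atypical protein kinase Prkci (-0.39 ± 0.13) and the adaptor Nck2 (-0.25 ± 0.08) fell. The list as a whole stood lower (median -0.18, camera adjusted p = 0.025, and adjusted p = 0.65 with an estimated correlation). Of 37 podocyte identity genes, 4 rose and 4 fell, or 3 and 11 with arrays centred. Rab3b (0.57 ± 0.14) and Clic3 (0.63 ± 0.17) rose, and Thsd7a (-0.53 ± 0.13) and the transcription factor Foxc2 (-0.30 ± 0.08) fell; the list stood lower (median -0.15, camera adjusted p = 0.023, and 0.76 with an estimated correlation). The slit diaphragm call was lost without WT array 7 (camera adjusted p = 0.062) or KI 24 (0.054), and the podocyte identity call without WT 10 (0.079) or KI 26 (0.075). Without WT 8 the podocyte identity median was -0.09. The tubule covariate took the medians to -0.06 for the slit diaphragm and -0.04 for the podocyte identity list, and no gene of either was called. Of 38 inherited podocyte disease genes, which share 8 with the identity list and 5 each with the slit diaphragm and basement membrane lists, 10 rose and 4 fell, or 8 and 8 with arrays centred (camera adjusted p = 0.99). The coenzyme Q genes Coq8b (1.47 ± 0.26) and Coq6 (0.84 ± 0.20) and the myosins Myo1e (1.34 ± 0.30) and Myh9 (1.76 ± 0.51) were among the rises.

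Actin regulators moved both ways at 5 weeks. Of 61 actin cytoskeleton genes, 11 rose and 5 fell (camera adjusted p = 0.9), the rises including the focal adhesion proteins Zyx (0.80 ± 0.15) and Tln1 (0.93 ± 0.20), the crosslinker Flna (1.70 ± 0.36) and Coro1b (0.72 ± 0.16). Of 28 basement membrane and integrin genes, 7 rose and 3 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.87). Tns1 (0.75 ± 0.16) and Ilk (0.48 ± 0.12) rose, and the collagen IV chains Col4a5 (-0.51 ± 0.15) and Col4a4 (-0.35 ± 0.11), of the mature membrane, fell. Of 20 injury genes, 6 rose and 0 fell in the limma fit, or 7 and 0 adjusted over the list alone (median 0.47, or 0.31 without WT array 7; camera adjusted p = 0.0069, and 0.65 with an estimated correlation). They included the TWEAK receptor Tnfrsf12a (0.70 ± 0.17), clusterin (Clu, 0.79 ± 0.21) and the keratins Krt18 (1.76 ± 0.43) and Krt19 (0.78 ± 0.22). The injury median was 0.20 with the tubule covariate and none was called. Of 12 parietal epithelium genes, 4 of which are also in the injury list, 3 rose and 1 fell (camera adjusted p = 0.87). Scin rose by 1.15 ± 0.36 and Ncam1 fell (-0.82 ± 0.25).

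Many mitochondrial and ribosomal genes rose. Of 70 oxidative phosphorylation genes 29 rose and none fell, or 36 rose and 1 fell adjusted over the list alone (median 0.24, camera adjusted p = 1.1e-06, and 0.65 with an estimated correlation). Uqcrc1 of complex III rose by 1.16 ± 0.22, Atp5o by 0.57 ± 0.10, Atp5j2 by 0.59 ± 0.11 and Cox6b1 by 0.52 ± 0.09. With the tubule covariate the list's median was 0.19, but none of its genes was called. Of 63 cytosolic ribosomal proteins 16 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.08, camera adjusted p = 0.031, and 0.76 with an estimated correlation), with Rplp0 (0.88 ± 0.17), Rpl23a (0.69 ± 0.12) and Rpl28 (0.66 ± 0.12) among them. With arrays centred 12 rose and 4 fell, and the call was lost without WT array 7 (camera adjusted p = 0.099), KI 24 (0.061) or KI 25 (0.051). The ribosomal median was 0.08 with the tubule covariate and none was called. Of 42 proteasome and ubiquitin genes, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.4). The 19S cap ATPases Psmc5 (0.91 ± 0.19) and Psmc3 (0.50 ± 0.11) rose, and so did Psmd9 (0.85 ± 0.17), which turned to -0.22 when all its probe sets were averaged. Of 34 unfolded protein response genes, 4 rose (1 with arrays centred) and 4 fell (camera adjusted p = 0.15), the falls including the chaperone genes Dnajc3 (-0.35 ± 0.08), Dnajb9 (-0.43 ± 0.11) and Dnajb11 (-0.43 ± 0.11) and the degradation gene Sel1l (-0.40 ± 0.12).

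Of 26 immediate-early genes 0 rose and 3 fell in the limma fit: Egr1 (-0.87 ± 0.30), Btg2 (-0.63 ± 0.21) and Csrnp1 (-0.63 ± 0.22). None fell adjusted over the list alone, and the list stood lower (median -0.37, camera adjusted p = 0.0075, and 0.65 with an estimated correlation). Without WT array 6 its median was -0.23 and it was not called (0.066), and with the tubule covariate the median was -0.16 and no gene was called. Of 37 fibrosis genes 2 rose, Snai1 (1.09 ± 0.25) and Col1a1 (camera adjusted p = 0.41). Of 28 interferon genes Irf7 rose (1.02 ± 0.26) and Ifih1 fell (-0.66 ± 0.17), with a camera adjusted p of 0.87. Of 37 cell cycle genes 3 rose, Cdk4 (0.47 ± 0.11) and Mcm7 (0.61 ± 0.18) among them, and 2 fell, Mcm4 (-0.54 ± 0.11) and Mad2l1 (-0.50 ± 0.15), with a camera adjusted p of 0.41. Of 20 senescence genes the lysosomal galactosidase Glb1 rose (0.98 ± 0.29), and Mdm2 (-0.51 ± 0.13) and Btg2 fell (camera adjusted p = 0.48). Adjusted over the list alone, the rises and falls were 1 and 0 for fibrosis, 4 and 5 for unfolded protein, 2 and 2 for cell cycle, 1 and 1 for senescence, 10 and 5 for inherited disease and 4 and 1 for parietal genes.

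Outside the parietal list, every marker of another cell type that passed at 5 weeks had risen. Of 24 endothelial genes 10 rose and none fell, or 16 adjusted over the list alone (median 0.68, camera adjusted p = 4.5e-05, and 0.65 with an estimated correlation), such as Robo4 (1.15 ± 0.25), Eng (1.62 ± 0.37), Plvap (1.45 ± 0.38) and Tie1 (1.28 ± 0.36). Of 26 loop, distal tubule and collecting duct genes 9 rose, 3 after quantile normalization, 4 with arrays centred, or 13 adjusted over the list alone (median 0.63, camera adjusted p = 0.00046, and 0.65 with an estimated correlation), such as Fxyd4 (1.01 ± 0.21) and the sodium channel subunit Scnn1b (1.13 ± 0.28). Of 23 proximal tubule genes 4 rose (median 0.63, camera adjusted p = 0.0075, and 0.65 with an estimated correlation): Miox (1.26 ± 0.30), Ass1 (1.53 ± 0.37), Fbp1 (0.84 ± 0.27) and Cyp4b1 (2.33 ± 0.80). Of 20 leukocyte genes 6 rose (median 0.54, camera adjusted p = 0.008, and 0.65 with an estimated correlation), including Tyrobp (1.09 ± 0.25) and Cd74 (1.46 ± 0.40). Of 15 mesangial, pericyte and smooth muscle genes 4 rose, Des (1.28 ± 0.37), Cnn1 (0.60 ± 0.18), Notch3 (1.02 ± 0.35) and Myh11, or 5 adjusted over the list alone (camera adjusted p = 0.12). Of 5 erythroid genes Hbb-b2 (1.82 ± 0.62) and Slc4a1 (0.90 ± 0.33) rose (camera adjusted p = 0.51), and Slc4a1 turned to -0.09 with the tubule covariate. Medians with the tubule covariate were 0.09 for endothelium and 0.12 for leukocytes, and, as it is built from their own genes, 0.01 and -0.11 for the loop and proximal lists; none of their genes was called. Adding this covariate to the model left 17 called genes, the Gapdh 3′ minus 5′ covariate gave 1660, and leaving out WT arrays 7, 8 and 9 left 1.

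At 2 weeks no gene passed. By camera at the preset correlation, lists of tubule and endothelial markers stood higher in KI and the fibrosis and podocyte identity lists lower, but none was called with an estimated correlation. Of 11968 genes 0 passed in the limma fit (lowest adjusted p = 0.257), and 613 had an unadjusted p under 0.05 (5.12%). For 347 genes (2.9%) the arrays did not overlap, against 2.86% by chance. The smallest p-values belonged to the growth arrest gene Gadd45g (1.52 ± 0.28), the clotting factor subunit F13b (1.42 ± 0.30), the kinase Dmpk (1.10 ± 0.24), the acetyl-CoA carboxylase Acacb (1.25 ± 0.31) and Stat5a (0.62 ± 0.15) among higher values. Among lower values they belonged to the microtubule-binding Eml2 (-0.88 ± 0.21), Zfp687 (-0.51 ± 0.12), the kinase inhibitor Cdkn2d (-0.51 ± 0.13), Wdr92 (-0.55 ± 0.14) and Clasp1 (-0.57 ± 0.16); none of these passed. Gadd45g was the only gene to pass when adjusted over its list alone, among senescence genes.

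For each list that camera called, parentheses from here on give the median log2 fold change, the camera adjusted p and the adjusted p with an estimated correlation, in this order. The proximal tubule list (median 0.63, camera adjusted p = 1.4e-11, and 0.24 with an estimated correlation) and the loop and distal list (0.47, 1.4e-11 and 0.26) stood highest at 2 weeks. The endothelium (0.32, 8.5e-07 and 0.45), leukocyte (0.13, 0.012 and 0.65) and oxidative phosphorylation lists (0.04, 0.0044 and 0.73) also stood higher. The fibrosis list stood lower (median -0.32, camera adjusted p = 1.3e-05, and 0.45 with an estimated correlation), with Postn at -0.90 ± 0.44, Mmp9 at -0.79 ± 0.26 and Mmp14 at -0.66 ± 0.27, none of them passing. With the tubule covariate its median was -0.36, while those of the podocyte identity (-0.05), oxidative phosphorylation (0.00), endothelium (-0.14) and leukocyte lists (-0.09) shrank or turned. The podocyte identity list stood at -0.15 (1.3e-05; 0.45), with Cdkn1c at -0.42 ± 0.15 and Sulf1 at -0.36 ± 0.15. Without WT array 1 it stood at -0.05 and was not called (camera adjusted p = 0.054), and the fibrosis list stood at -0.21. Without KI array 22 the loop and distal list stood at 0.29 and the endothelium list at 0.06. The oxidative phosphorylation call was lost without WT array 1, WT 2 or KI 21 (0.39, 0.069 and 0.13), and the leukocyte call without WT 2, WT 5 or KI 19 (0.076, 0.091 and 0.12). Actn1 (0.31 ± 0.24) and Col1a1 (-0.46 ± 0.41) did not pass.

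At 44 weeks 3 genes passed. The predicted gene Gm38983 and the glutathione-dependent oxidoreductase Glrx (1.64 ± 0.28, limma adjusted p = 0.032) rose, and the immunoglobulin segment Igkv1-135 fell (-1.43 ± 0.23, adjusted p = 0.022). At an unadjusted p under 0.05 there were 762 genes, and the arrays did not overlap for 328 genes (2.74%, against 2.86% by chance). Actn1 (0.65 ± 0.24, adjusted p = 0.69) and Col1a1 (0.00 ± 0.41) did not pass. Other values that did not pass were those of Cxcl1 (1.15 ± 0.34), Egr1 (0.98 ± 0.32), Maff (0.75 ± 0.24), the joining chain Jchain (-1.72 ± 0.41), Dach1 (-0.49 ± 0.18), Lmx1b (-0.45 ± 0.17) and Col4a3 (-0.41 ± 0.15). With the sex covariate 1 gene remained called, while the median signed fold of the 3 genes was 1.683, against 1.645 without it. Without WT array 15 there were 45 called genes, against 1 without WT 17 or KI 31. Array weights gave 267.

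Among gene groups at 44 weeks the podocyte identity list stood lower in KI (median -0.16, camera adjusted p = 1.2e-07, and 0.52 with an estimated correlation), as did interferon genes (-0.11, 0.0083 and 0.52). The immediate-early list stood higher (median 0.32, camera adjusted p = 9.9e-05, and 0.52 with an estimated correlation). The injury (0.17, 0.022 and 0.59), mesangium (0.19, 0.022 and 0.59), endothelium (0.42, 1e-04 and 0.59) and proximal tubule lists (0.35, 9.9e-05 and 0.52) also stood higher. Only the podocyte identity call was kept without each single array, with a median of -0.27 without WT array 15. Without WT 15 the immediate-early (camera adjusted p = 0.15) and interferon calls (0.19) were lost. Without WT 16 the endothelium (0.077), proximal tubule (0.077), mesangium (0.077) and injury calls (0.18) were lost. Without KI 33 the mesangium (0.14), injury (0.061) and interferon calls (0.061) were lost, without KI 31 the injury call (0.18), and without WT 17 or WT 18 the mesangium call (0.067 and 0.058). After adding the tubule covariate the medians were -0.11 for podocyte identity, -0.17 for interferon, 0.37 for immediate-early, 0.05 for injury, 0.13 each for mesangium and endothelium, and 0.15 for proximal tubule genes.

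Averaged over the 3 ages, 637 genes passed, 478 higher and 159 lower in KI, and 524 of them were also called at 5 weeks. The count was unstable: leaving out single arrays gave 101 (without KI 2-week array 22) to 1828 (without WT 44-week array 15), and 19 of 25 such runs changed it by more than 1.5 times. Array weights gave 3109. The share of higher calls was 75%, and 61.7% after quantile normalization. The hydroxyproline dehydrogenase Prodh2 rose by 1.10 ± 0.14 (limma adjusted p = 0.00017) and was the only tested gene whose KI and WT arrays did not overlap at any of the ages. Actn1, the closest actinin paralog, rose by 0.47 ± 0.14 (adjusted p = 0.046). Other rises were in Tns1 (0.57 ± 0.10), the laminin chain Lama1 (0.90 ± 0.23), Zyx (0.40 ± 0.09), Myo1e (0.74 ± 0.18), Myh9 (1.16 ± 0.30), Myh10 (1.53 ± 0.40), Myh11 (1.92 ± 0.53), Gadd45g (0.77 ± 0.16), the complement gene Cfb (0.87 ± 0.23), Krt18 (1.09 ± 0.26), Herpud1 (0.49 ± 0.11) and Coq8b (0.73 ± 0.15). Thsd7a (-0.39 ± 0.08), Foxc2 (-0.18 ± 0.05), Fyn (-0.29 ± 0.08), E2f1 (-0.59 ± 0.14) and Psmd11 (-0.54 ± 0.15) fell. With the tubule covariate Myh10 and Myh11 turned to -0.09 and -0.25, and 4 genes were called. Col1a1 did not pass (0.21 ± 0.24).

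In that average 2 of 37 podocyte identity genes fell, or 10 adjusted over the list alone (median -0.14, camera adjusted p = 3e-07, and 0.41 with an estimated correlation). The slit diaphragm list also stood lower (-0.14, 0.0054 and 0.41). Of 70 oxidative phosphorylation genes 8 rose, or 16 adjusted over the list alone (median 0.09, camera adjusted p = 1.2e-06, and 0.5 with an estimated correlation), including Ndufs1 (0.89 ± 0.20) and Sdha (0.54 ± 0.13). Of 24 endothelial genes 6 rose, or 20 adjusted over the list alone (0.55, 4.5e-09 and 0.41), including Pecam1 (0.68 ± 0.16). Of 23 proximal tubule genes 4 rose, or 17 adjusted over the list alone (0.59, 1.7e-08 and 0.41). The injury (0.18, 0.0018 and 0.41) and leukocyte lists (0.29, 0.0018 and 0.45) stood higher as well, with 3 and 2 called rises. Adjusted over the list alone, 5 injury genes rose, and 4 leukocyte genes rose and 1 fell. Of the loop and distal tubule genes 1 rose, or 13 adjusted over the list alone (median 0.37, camera adjusted p = 1.8e-06, and 0.41 with an estimated correlation). Of 61 actin genes 8 rose and 1 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.88). Of 28 basement membrane genes 2 rose, while adjusted over the list alone 5 rose and 6 fell. Medians with the tubule covariate were -0.05 for podocyte identity, -0.02 for slit diaphragm, 0.06 for oxidative phosphorylation, 0.05 for injury, 0.03 for endothelium, 0.04 for leukocyte, 0.07 for proximal and -0.06 for loop and distal genes, with none of them called.

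Genes on chromosome 7 near Actn4 passed more often than others. Within 20 Mb of the locus 32 of 346 tested genes (9.25%) were called in the average over ages, against 5.21% elsewhere (odds ratio 1.86, 95% interval 1.24 to 2.70, Fisher's exact p = 0.0022). At 5 weeks the shares were 30.3% and 21.8% (odds ratio 1.56, 1.23 to 1.98, exact p = 0.00028). At 44 weeks 1 of the 3 called genes lay there (exact p = 0.084). Fisher's test takes genes as independent, which genes measured on the same arrays are not, so these p-values may be too small. Of the called genes there, 29 of 32 in the average and 92 of 105 at 5 weeks were higher in KI. Among all called genes the shares higher in KI were 75% and 64.8%. The 4 genes there with the smallest p-values were Gm38983 (1.34 ± 0.13), Dmpk (1.16 ± 0.14), Prodh2 (1.10 ± 0.14) and Eml2 (-0.76 ± 0.12), with limma adjusted p = 5.2e-06, 0.00013, 0.00017 and 0.0077; apart from Prodh2 they were singled out here after their values were seen.

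**Figure D3:**
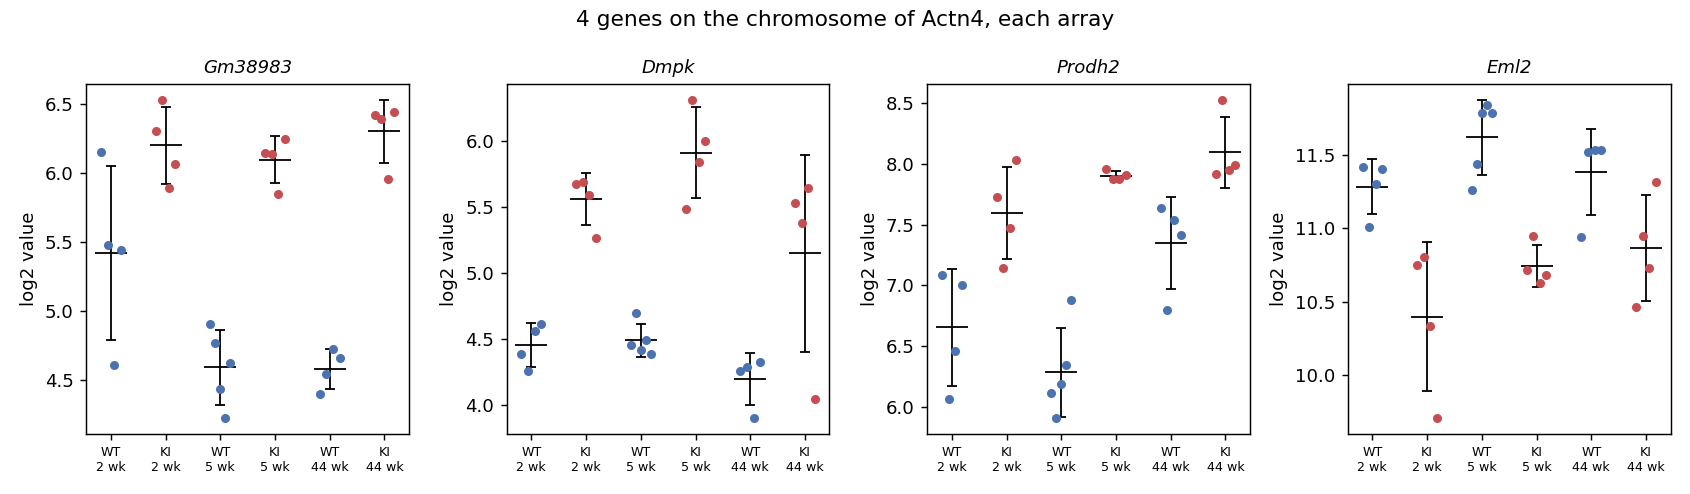
Log2 values in each array (points; bars are group mean and SD) for Gm38983, Dmpk, Prodh2 and Eml2, by genotype (blue WT, red KI) and age. Averaged over ages, KI exceeded WT by 1.34, 1.16 and 1.10 for the first 3 and differed by -0.76 for Eml2.

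The genotype effect was compared between ages by interaction terms. The effect at 5 weeks exceeded that at 2 weeks for 3 genes: Mri1, of methionine salvage (1.62 ± 0.24, limma adjusted p = 0.013), the DNA repair gene Tdp1 (1.35 ± 0.23, 0.034) and the membrane-curving Trip10 (1.13 ± 0.19, 0.034); 2242 genes had an unadjusted p under 0.05. Leaving out single arrays gave 0 to 1521 genes, the highest without WT 5-week array 10, array weights gave 2441, and the Gapdh 3′ minus 5′ covariate gave 0. From 5 to 44 weeks 0 genes passed in limma (2335 at an unadjusted p under 0.05, lowest adjusted p = 0.0941), but 1561 without WT 5-week array 10 and 2041 with array weights. From 2 to 44 weeks 0 passed (359). Whether the effect at 5 weeks differs from the other ages thus depends on array 10 and on the weighting. By camera the rise of oxidative phosphorylation genes was larger at 5 than at 2 weeks (adjusted p = 0.0026, and 0.82 with an estimated correlation), with 13 of its genes and 12 ribosomal protein genes passing when adjusted over the list alone. It also called the fibrosis (0.0073) and injury lists (0.043) upward. From 5 to 44 weeks camera called the immediate-early list upward (4.8e-06) and the oxidative phosphorylation (4.8e-06), loop and distal tubule (0.00041) and ribosomal lists (0.0067) downward. From 2 to 44 weeks it called the immediate-early (3.6e-06) and fibrosis lists (6.6e-05) upward and the loop and distal list downward (1.1e-08). With an estimated correlation none of these was called (lowest adjusted p = 0.52). Across genes, which are not independent replicates, fold changes correlated between 2 and 5 weeks (Pearson r = 0.313, Spearman 0.232), 2 and 44 weeks (0.275, 0.252) and 5 and 44 weeks (0.359, 0.249). The jackknife standard errors of r were 0.146, 0.206 and 0.245, and with the tubule covariate the values became -0.013, 0.00622 and 0.0509.

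Between 2 and 5 weeks in WT, most genes of the fibrosis, cell cycle and respiratory chain lists fell, and most of the podocyte identity and slit diaphragm lists rose. Embryonic collagen IV and laminin chains were among the falls. In the limma fit 4053 genes passed, 1457 higher and 2596 lower at 5 weeks, with 136 and 886 beyond 2-fold. Arrays did not overlap for 2003 genes (16.7%, against 1.59% by chance). The share of higher calls was 35.9%, 44.1% after quantile normalization and 43.1% with arrays centred. The actin 3′ minus 5′ signal was 1.52 at 5 weeks and 1.19 at 2 weeks (exact permutation p = 0.0079, adjusted 0.08), and leaving out WT arrays 7, 8 and 9 left 991 called genes. With the Gapdh 3′ minus 5′ covariate 2572 were called, and with array weights 6092. The hybridization controls averaged 10.72 at 5 weeks and 10.41 at 2 weeks (exact permutation p = 0.032, adjusted 0.12). Their values did not overlap (10.46 to 11.06 and 10.35 to 10.45), so a difference in the assay cannot be told apart from age. Y-linked signal was high in 2 of 5 and 4 of 4 arrays. With the sex covariate 3316 of the 4053 genes were still called.

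The largest fall was that of Serpina6, the corticosteroid-binding globulin, at -7.65 ± 0.54 (limma adjusted p = 1.5e-08). The renin-angiotensin genes Agt (-3.93 ± 0.52, 2.1e-05) and Ace (-3.48 ± 0.51, 6.4e-05) fell too, as did the clotting regulator Serpina10 (-3.40 ± 0.49), the matrix genes Postn (-3.37 ± 0.42), Smoc2 (-3.18 ± 0.50) and Adam12 (-3.25 ± 0.55), the peptide hormone Cck (-3.24 ± 0.39), the homeobox gene Alx1 (-3.15 ± 0.42), the aminopeptidase Xpnpep2 (-3.11 ± 0.48) and the globins Hbb-b2 (-3.83 ± 0.62) and Hba-a1 (-3.15 ± 0.53). Globin genes have near-identical copies that a probe set may not separate, and the same holds for the Akr1c genes. The steroid dehydrogenases Akr1c18 (3.68 ± 0.69, 0.00044) and Akr1c14 (3.36 ± 0.69, 0.0009), the acetyltransferase Nat8 (3.07 ± 0.50, 0.00014) and the lectin Clec2h (2.59 ± 0.42, 0.00014) rose. Neuroglobin (Ngb, 2.54 ± 0.30), Cyp2a5 (2.54 ± 0.40), the transporters Slc22a22 (2.41 ± 0.60) and Slc10a2 (2.15 ± 0.47), Mogat1 (2.40 ± 0.58), Tlr7 (2.18 ± 0.34), the complement gene C8a (2.18 ± 0.35) and Acpp (2.15 ± 0.30) rose as well.

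Of 37 podocyte identity genes 21 rose and 2 fell from 2 to 5 weeks, or 24 and 2 adjusted over the list alone (median 0.35, camera adjusted p = 1.1e-06, and 0.31 with an estimated correlation). Vegfa (0.77 ± 0.11), Wt1 (0.41 ± 0.08) and Foxc2 (0.44 ± 0.08) rose, and the prostaglandin synthase Ptgds fell (-2.57 ± 0.45). Of 18 slit diaphragm genes 10 rose and 2 fell (0.34, 0.00054 and 0.31), with Nck2 (0.55 ± 0.08), Fyn (0.70 ± 0.13) and Cd2ap (0.51 ± 0.11) up and Sh3kbp1 (-1.90 ± 0.29) down. Of 37 fibrosis genes 24 fell and 1 rose (median -1.08, camera adjusted p = 1.1e-06, and 0.31 with an estimated correlation), such as Eln (-2.71 ± 0.26), Mmp2 (-2.79 ± 0.39) and Snai1 (-1.94 ± 0.25). Of 37 cell cycle genes 19 fell and none rose, or 22 and 1 adjusted over the list alone (-0.73, 0.00015 and 0.31), such as Mcm5 (-1.01 ± 0.15) and Cdk4 (-0.66 ± 0.11). Of 70 oxidative phosphorylation genes 43 fell and none rose, or 47 adjusted over the list alone (-0.33, 1.9e-09 and 0.31), such as Ndufs8 (-1.21 ± 0.18). The mean of this list went from 11.63 to 11.24 in WT and from 11.70 to 11.55 in KI. Of 63 ribosomal proteins 22 fell and 1 rose, or 23 and 2 adjusted over the list alone (-0.13, 0.0076 and 0.77), a call lost without WT 2-week array 2 (camera adjusted p = 0.06). Of 15 mesangial genes 11 fell (-0.91, 0.00089 and 0.31), such as Acta2 (-1.29 ± 0.17) and Rgs5 (-1.65 ± 0.29).

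Basement membrane and actin genes changed in part. Of 28 basement membrane genes 9 fell and 2 rose (camera adjusted p = 0.35), among them Col4a1 (-1.94 ± 0.24), Col4a2 (-1.92 ± 0.25), Lamb1 (-1.97 ± 0.26) and Lamc1 (-1.08 ± 0.17). Of 61 actin genes 11 rose and 12 fell (0.75), with Zyx (-1.53 ± 0.15), Myl9 (-1.68 ± 0.22) and Tpm2 (-1.61 ± 0.23) down. Of 20 injury genes 7 fell (-0.48, 0.028 and 0.47), and of 12 parietal genes 7 fell (-0.59, 0.035 and 0.31), with Krt8 in both lists (-2.52 ± 0.49). Of 28 interferon genes 4 rose, 7 after quantile normalization or with arrays centred, and 1 fell (0.21, 0.02 and 0.38). The injury call was lost without WT 2-week array 1 (camera adjusted p = 0.057) or 5-week array 7 (0.096), and the parietal call without 2-week array 2 (0.085) or 5-week array 10 (0.16). The interferon call was lost without 2-week array 2 (0.085, median 0.13) or 5-week array 6 (0.066). Xaf1 rose by 1.30 ± 0.33 but turned to -0.43 when its probe sets were averaged. Camera called none of the proximal tubule (5 rose, 3 fell, adjusted p = 0.38), loop and distal (2 rose, 3 fell, 0.86), endothelium (1 rose, 2 fell, 0.95) and leukocyte lists (1 rose, 1 fell, 0.38). Nor did it call the senescence (5 rose, 4 fell, 0.75), immediate-early (1 rose, 4 fell, 0.75), unfolded protein (1 rose, 8 fell, 0.75), proteasome (4 rose, 11 fell, 0.43), inherited disease (10 rose, 6 fell, 0.31) and erythroid lists (2 fell, 0.35). The balance turned with scaling for the immediate-early list (5 rose and 3 fell after quantile normalization, 4 and 4 with arrays centred) and the actin list (14 and 11 with arrays centred). Adjusted over the list alone, the rises and falls were 5 and 12 for proteasome, 5 and 5 for senescence, 2 and 2 for loop and distal, 0 and 2 for endothelial and 0 and 1 for leukocyte genes.

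From 5 to 44 weeks in WT, the largest rises included Pigr, Jchain and 2 immunoglobulin light chain segments, and the largest falls Col3a1 and Col1a1. Of the respiratory chain genes 24 of 70 rose (13 with arrays centred, where 3 fell), and of the actin genes 14 of 61 fell and 5 rose (21 and 2 with arrays centred). In the limma fit 2408 genes passed, 1349 higher and 1059 lower at 44 weeks, and arrays did not overlap for 1454 genes (12.1%, against 1.59% by chance). With only the arrays compared, 558 of the 2408 were still called, and 645 were without WT 5-week arrays 7, 8 and 9. The hybridization controls, which are added during the assay, averaged 9.98 at 44 weeks and 10.72 at 5 weeks in WT, and 9.77 and 10.64 in KI. A difference in the assay therefore cannot be told apart from age. The share of higher calls was 56%, 37.3% after quantile normalization and 33% with arrays centred, where the median of all genes moved from 0.05 to -0.05. The polymeric immunoglobulin receptor Pigr rose by 5.67 ± 0.45 (limma adjusted p = 9.5e-08), Jchain by 4.86 ± 0.39 (9.5e-08), and the light chain segments Igkj1 by 4.42 ± 0.51 (1.1e-05) and Igkv1-135 by 2.34 ± 0.22 (8.3e-07). The methyltransferase Bhmt (3.36 ± 0.68), Aldh1a7 (3.33 ± 0.72), Creg2 (2.91 ± 0.36), the water channel Aqp4 (2.82 ± 0.69), Apob (2.55 ± 0.32), Astn1 (2.42 ± 0.40), the peptidase Folh1 (2.41 ± 0.37) and Serpina1b (2.31 ± 0.58) also rose.

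The defensin Defa21 fell by 3.49 on the log2 scale (SE 0.30, limma adjusted p = 2.8e-07), and so did Col3a1 (-2.58 ± 0.32), Col1a1 (-2.24 ± 0.39), Col6a1 (-1.67 ± 0.29), Nrep (-2.18 ± 0.19), the histone gene H2bu2 (-2.04 ± 0.30), Nav3 (-1.86 ± 0.43), Egr1 (-1.75 ± 0.30), Obox2 (-1.64 ± 0.29), the actin-binding Cotl1 (-1.62 ± 0.20), pleiotrophin (Ptn, -1.60 ± 0.33) and Tpgs2 (-1.59 ± 0.17). Col1a1 is also the gene whose promoter drives the ribosome tag.

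**Figure D4:**
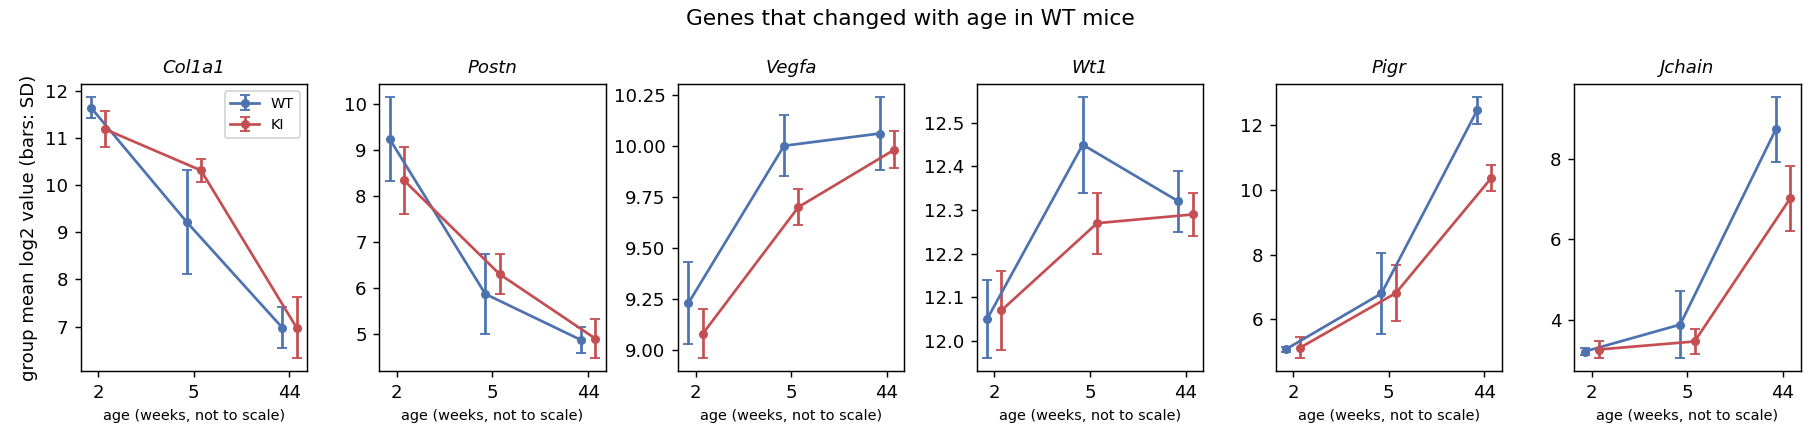
Group mean log2 value (y axis; bars are SD) at 2, 5 and 44 weeks for Col1a1, Postn, Vegfa, Wt1, Pigr and Jchain in WT (blue) and KI (red). In WT, Vegfa rose by 0.77 from 2 to 5 weeks and Pigr by 5.67 from 5 to 44 weeks.

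Of 37 fibrosis genes 10 fell and 1 rose from 5 to 44 weeks (median -0.27, camera adjusted p = 0.00011, and 0.52 with an estimated correlation), including Eln (-1.44 ± 0.26). Of 37 cell cycle genes 10 fell and none rose, or 13 adjusted over the list alone (-0.39, 0.00011 and 0.5), such as Ccnd2 (-1.30 ± 0.21) and Top2a (-1.33 ± 0.34). Of 61 actin genes 14 fell and 5 rose, or 16 and 5 adjusted over the list alone (median -0.06, camera adjusted p = 0.016, and 0.5 with an estimated correlation), such as Arpc4 (-0.54 ± 0.08), Cfl1 (-0.35 ± 0.06) and Rhoc (-0.71 ± 0.14). With arrays centred 21 fell and 2 rose (median -0.17), and with the tubule covariate 6 fell and 1 rose. Of 26 immediate-early genes 4 fell (-0.39, 0.0015 and 0.52), and of 15 mesangial genes 3 fell (-0.36, 0.023 and 0.55). Of 70 oxidative phosphorylation genes 24 rose and none fell, or 29 adjusted over the list alone (0.20, 4.3e-05 and 0.55), such as Ndufb3 (0.71 ± 0.13). With arrays centred 13 rose and 3 fell, with a median of 0.10. Of 34 unfolded protein genes 6 rose and 1 fell (0.26, 0.0075 and 0.52), including the sensors Ern1 (0.89 ± 0.16) and Eif2ak3 (0.71 ± 0.15). Of 63 ribosomal proteins 18 rose and 3 fell (camera adjusted p = 0.013, and 0.72 with an estimated correlation). Their median was 0.07, and -0.03 with arrays centred, where 11 rose and 8 fell. The ribosomal call was lost without WT 44-week array 16 (camera adjusted p = 0.064) or 5-week array 7 (0.05 after rounding), and the mesangial call without WT 5-week array 6 (0.15, median -0.13) or 10 (0.1) or 44-week array 16 (0.068) or 17 (0.051, median -0.21). The immediate-early median was -0.23 without 5-week array 6 or 44-week array 15, and that of fibrosis -0.45 without 5-week array 7 and -0.41 without 44-week array 17. After adding the tubule covariate the medians were -0.06 for immediate-early (0 fell), -0.42 for fibrosis (5 fell), -0.32 for cell cycle (3 fell), -0.61 for mesangial (2 fell), 0.13 for oxidative phosphorylation (5 rose), 0.38 for unfolded protein (4 rose) and 0.09 for ribosomal genes (6 rose).

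Of 20 leukocyte genes 8 rose, or 11 adjusted over the list alone (0.67, 0.00014 and 0.52), such as the lysosomal Laptm5 (0.90 ± 0.16). Of 26 loop and distal tubule genes 11 rose, or 17 adjusted over the list alone (0.65, 8.9e-06 and 0.52), such as the transcription factor Foxi1 (1.14 ± 0.28). Of 23 proximal tubule genes 3 rose (0.55, 0.017 and 0.61), such as Slc4a4 (1.23 ± 0.33). None of 24 endothelial genes passed in limma, though the list stood higher (0.47, 0.022 and 0.72). Of 20 injury genes 5 rose (0.39, 0.044 and 0.55), such as Clu (1.00 ± 0.21). Krt18 (1.23 ± 0.43) rose, and turned to -0.39 with the tubule covariate. Without WT 44-week array 15 the proximal tubule and endothelium lists were not called (camera adjusted p = 0.34 each, medians 0.34 and 0.30), nor were they without 5-week array 7 (0.07 and 0.14). The endothelium call was also lost without 5-week array 8 (0.056) or 44-week array 17 (0.051). The injury call was lost without 5-week arrays 7, 8 or 9, 44-week arrays 15, 17 or 18, or 2-week array 1 (0.055 to 0.2). The endothelium (-0.35) and proximal tubule medians (-0.32) reversed with the tubule covariate, the injury median was -0.02, that of the loop and distal list 0.04 and that of leukocyte genes 0.17, with 1 call left in each of the last 2. Of 37 podocyte identity genes 6 rose and 2 fell, or 5 and 5 with arrays centred (camera adjusted p = 0.59), the rises including Srgap1 (1.28 ± 0.15), Cdkn1c (0.61 ± 0.14) and Lmx1b (0.60 ± 0.16). Camera called none of the slit diaphragm (1 rose, 3 fell, adjusted p = 0.28), basement membrane (4 rose, 5 fell, 0.58), interferon (1 rose, 2 fell, 0.99) and proteasome lists (8 rose, 4 fell, 0.66). Nor did it call the senescence (1 rose, 0.71), inherited disease (8 rose, 4 fell, 0.81), parietal (1 rose, 0.59) and erythroid lists (none passed, 0.99). With arrays centred the rises and falls were 4 and 6 for inherited disease, 0 and 2 for parietal, 6 and 6 for proteasome, 0 and 3 for interferon and 3 and 8 for basement membrane genes, and after quantile normalization inherited disease genes had 5 and 5. Adjusted over the list alone, the rises and falls were 6 and 3 for podocyte identity, 4 and 7 for basement membrane, 6 and 0 for injury, 7 and 1 for unfolded protein, 9 and 5 for proteasome, 21 and 5 for ribosomal and 8 and 5 for inherited disease genes, with none in the interferon and parietal lists. Fat1 (-0.37 ± 0.09), Nid1 (-1.21 ± 0.19) and Col4a4 (-0.54 ± 0.11) fell. Prkci (-0.40 ± 0.13) and Podxl (-0.21 ± 0.07) fell too, but turned to 0.07 and 0.20 when their probe sets were averaged. The tubule marker mean was 0.70 higher at 44 weeks (exact permutation p = 0.04, adjusted 0.12), and with it as a covariate 788 genes were called. The actin 3′ minus 5′ signal was 0.99 at 44 weeks and 1.52 at 5 weeks (exact p = 0.0079, adjusted 0.08), and with that covariate 780 were called. The 18S 5′ signal was 11.04 at 44 weeks and 8.74 at 5 weeks (exact permutation p = 0.016, adjusted 0.08) and was not used as a covariate. Array weights gave 3762.

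The genotype effect at 5 weeks and both age comparisons use the same WT 5-week arrays. The oxidative phosphorylation list averaged 11.63, 11.24 and 11.47 in WT at 2, 5 and 44 weeks, and 11.70, 11.55 and 11.51 in KI. Its fall and later rise in WT and its higher level in KI at 5 weeks thus share the low WT 5-week mean. Of genes called in both, 1083 were lower at 5 than at 2 weeks in WT and higher in KI at 5 weeks (371 if the lists were independent), and 442 moved the opposite way (113). The shared arrays alone produce an excess over independence, so these counts are not evidence of a link. The correlation of the fold changes across genes was -0.513. With simulated unchanged groups it averaged -0.491 (range -0.872 to 0.00977), and with the controls split -0.363. The covariance was -0.143 against a simulated mean of -0.0253, a difference of -0.117 for which no spread is given. With the change from 5 to 44 weeks in WT, 562 genes rose in both (193) and 261 fell in both (82.1). That correlation was 0.464, against 0.396 simulated (range -0.441 to 0.782) and 0.282 with split controls, and the covariance 0.097 against 0.022. The age comparisons correlated with each other at -0.15, against -0.449 simulated (range -0.821 to 0.229) and -0.0284 with split controls. Their covariance was -0.0412, against -0.0252 simulated and -0.00789 with split controls.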

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

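Of the tests here, the smooth muscle comparison, the tests of sex, the runs without WT 5-week arrays 7, 8 and 9 and the runs with actin or Gapdh 3′ minus 5′ covariates were chosen only after the results were seen.

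Single arrays stood far from the others of their group in 18 of 204 group measures, against 10.2 expected by chance at 5%. Among list means (log2) these were slit diaphragm in WT 2-week array 1 at 10.15 (others 9.88 to 9.91), basement membrane in KI 2-week array 22 at 9.84 (9.96 to 9.97) and cell cycle in WT 2-week array 2 at 7.53 (7.01 to 7.08). KI 2-week array 19 stood apart in the unfolded protein response at 8.65 (8.74 to 8.75) and in erythroid genes at 8.71 (9.41 to 9.53). WT 5-week array 6 stood apart in interferon genes at 7.66 (7.31 to 7.38) and erythroid genes at 8.73 (7.47 to 7.69), KI 5-week array 23 in interferon genes at 7.35 (7.51 to 7.53), and KI 5-week array 26 in parietal genes at 8.05 (7.60 to 7.63). Among control measures these were the hybridization controls of KI 2-week array 20 at 10.33 (10.46 to 10.48) and the actin 3′ minus 5′ signal of KI 44-week array 34 at 1.85 (0.99 to 1.06). The Gapdh 3′ minus 5′ signal of WT 5-week array 10 was 1.91 (0.98 to 1.15), and the 18S 5′ signal of KI 5-week array 26 was 9.64 (10.50 to 10.52).

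Near Actn4, Gm38983 in KI 44-week array 33 was 5.96 (others 6.39 to 6.44), Prodh2 in KI 44-week array 32 was 8.53 (7.92 to 7.99), and Eml2 in WT 44-week array 15 was 10.94 (11.52 to 11.53). Dmpk in KI 44-week array 34 was 4.05 (5.38 to 5.65), a level of the WT arrays, and in WT 44-week array 17 it was 3.90 (4.26 to 4.33). In array 34 Eml2 was also at a WT level, while Gm38983 and Prodh2 were not.

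The genotype effect differed between 5 and 2 weeks, by a limma interaction term, for Mri1 (1.62), Tdp1 (1.35) and Trip10 (1.13). Outside the named genes, 588 of 10911 probe sets without a gene name here passed at 5 weeks between KI and WT. The hybridization control signal, which is added during the assay, changed by -0.74 between WT 5 and WT 44 weeks (exact permutation p = 0.0079, adjusted 0.08).

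Regrouping the arrays showed how often other splits gave as many calls. For KI against WT at 5 weeks 2 of 100 splits, the real one included, gave as many called genes as the real 2638; the other gave 4328 and set WT arrays 6 to 9 against the KI arrays with WT array 10. For the average over ages 2 of 100 gave as many as 637 (highest other 1627). For WT at 5 against 2 weeks 2 of 100 gave as many as 4053 (4485, a split that moved WT array 10 to the 2-week arrays), and for 44 against 5 weeks 2 of 100 gave as many as 2408 (2805). For the interaction of 5 and 2 weeks 3 of 100 gave as many as 3 genes (highest other 1055). As many calls were thus rare among these splits, unadjusted over the tests, which makes chance less likely but does not exclude it. The interaction is apart from this, since its splits also removed the genotype effect common to both ages and so do not test it alone. Its 3 genes also became 0 to 1521 when single arrays were left out. Splits with several times the real count, as in the interaction and the average, point to a structure within the samples. At 44 weeks as many calls were not rare (3 of 35, real 3, highest other 183, a split that set KI array 34 with WT arrays 16, 17 and 18). Where the real count is 0 every split gives as many, so the splits decide nothing at 2 weeks (35 of 35, highest other 4) or for the other interactions (100 of 100 for each, highest others 242 and 48).

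For the gene lists that camera called, chance is not excluded at 2 weeks (19 of 35 splits gave as many as 7, highest other 12), 5 weeks (14 of 100, real 10, highest other 12), 44 weeks (10 of 35, real 7, highest other 10), the average (31 of 100, real 8, highest other 15) or WT 5 against 2 weeks (20 of 100, real 10, highest other 11). For WT 44 against 5 weeks only the real grouping gave as many (1 of 100, real 13, highest other 12), unadjusted over the tests.

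The first pattern weighed is the 5-week genotype difference of 2638 genes. RNA integrity as its cause was tested only through the actin and Gapdh controls, which did not take up the fold. With the actin 3′ minus 5′ covariate the called genes kept 103% (SE 4.93) of their median fold (1644 of 2638 still called). With that of Gapdh they kept 87.1% (SE 18.2, 1555 still called). At 5 weeks the actin signal did not overlap between KI (at most 1.33) and WT (at least 1.47). Its slope therefore came from the spread within groups, widest in KI at 44 weeks (SD 0.41). The 18S 5′ signal, 10.30 in KI and 8.74 in WT, was not used as a covariate. Sex is argued against as the whole cause, since with the sex covariate 99.6% (SE 4.97) was kept and 2110 were still called. The count for the average went from 637 to 421, with 95.6% of the median fold of those 637 genes kept. Tubule RNA in the precipitate as the whole cause was tested with the tubule covariate, which cannot decide it. With the tubule covariate the median fold went from 0.62 to 0.41 and 65.8% (SE 15.7) was kept. The limit set beforehand was 50%, barely cleared with a margin of 1 SE that was chosen afterwards. The calls ended (17 left) because the covariate took up part of the fold and the median standard error of these genes went from 0.168 to 0.201. With the same covariate the 637 genes called in the average over ages kept 35.2%, under that limit, and 4 were still called. At 5 weeks the tubule marker mean did not overlap between KI (at least 8.61) and WT (at most 8.40). The slope of this covariate therefore also came from the spread within groups. Tubule RNA thus stays open for the 5-week genes and for the average. That WT 5-week arrays 7, 8 and 9 differ from arrays 6 and 10 cannot be told apart from genotype, since 67.0% (SE 40) of the fold was kept without them and 1 gene was called. Array background differed as well at 5 weeks. The signal of high-GC minus low-GC background probes was 1.01 to 1.24 in KI and 0.79 to 0.94 in WT. It was not used as a covariate, so its part was not tested. The knock-in itself, RNA integrity, array background and the composition of the purified RNA stay open, so no biological cause is claimed.

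The second pattern is the higher level of 21 myosin heavy chain genes in KI. Tubule RNA in the precipitate may account for it, since with the tubule covariate 1.63% (SE 16.0) of the median fold over ages was kept. Against this, from 5 to 44 weeks in WT the tubule marker mean rose by 0.70 and the myosin median by only 0.18. With the tubule covariate that myosin median turned to -1.068. The myosin genes thus did not follow the tubule markers between these ages, and tubule RNA stays open as the cause. The covariate also follows other RNA (it took the endothelium list's median from 0.55 to 0.03), so the test does not name the cell. RNA integrity was tested only through the actin and Gapdh controls, which did not take up the fold. With the actin covariate 102% (SE 11.3) was kept, and with that of Gapdh 97.9% (SE 21.2). At 5 weeks the actin signal did not overlap between KI and WT, so its slope came from the spread within groups. The ribosomal RNA signal was not used as a covariate. RNA integrity therefore stays open for the myosin genes. Sex is argued against as the whole cause, with 92.2% (SE 18.8) kept. Smooth muscle or mesangial RNA cannot be told apart from the knock-in: the other 14 genes of that list had an upper quartile of 0.57 at 5 weeks, between the lower quartile (0.47) and the median (1.47) of the myosin genes, and over ages 0.32 against a lower quartile of 0.35. At 2 weeks these genes stood lower in KI (median -0.168, upper quartile 0.127) and the myosin genes higher (median 0.833, lower quartile 0.177), which goes against smooth muscle RNA, but the gap of 0.05 between the quartiles is within its jackknife SE of 0.26. Without WT 5-week arrays 7, 8 and 9 the myosin median at 5 weeks was 0.667 (45.4% kept) and none was called.

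The third pattern is the excess of called genes near Actn4. In the average over ages the window around Actn4 had the highest share of 52 windows of the genome (1 of 52 with as high a share, 9.25% against 8.99% in the next), and at 5 weeks 2 of 52 had as high a share. A strain-derived segment linked to the knock-in allele may therefore explain it, given the mixed C57 and 129 background, and effects of the mutation on neighbouring genes were not tested. Tubule RNA cannot be told apart as a part of it, since of the 4 genes with the smallest p 2 stayed called with the tubule covariate, Gm38983 (1.34 to 1.38) and Dmpk (1.16 to 1.23), while Prodh2 (1.10 to 0.70) and Eml2 (-0.76 to -0.54) did not. Whether a probe differs in sequence between strains was not analysed here.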

How the results depend on the processing

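The runs without WT 5-week arrays 7, 8 and 9 and those with actin or Gapdh 3′ minus 5′ covariates were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because the groups compared share no replicate numbers. The planned offset on the linear scale was not run. Except where a setting's construction shows it (fewer arrays, fewer genes tested, a covariate correlated with genotype), the cause of a change was not tested.

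Array weights gave 4821 genes for KI against WT at 5 weeks, 267 at 44 weeks, 3109 for the average, 6092 for WT 5 against 2 weeks, 3762 for 44 against 5 weeks, and 2441 and 2041 for the interactions of 5 with 2 and 44 with 5 weeks. With only the arrays compared, 500 genes were called at 5 weeks, 2243 and 567 in the age comparisons and 0 in the interaction of 5 with 2 weeks. The tubule covariate left 17 genes at 5 weeks, 4 in the average and 788 for WT 44 against 5 weeks. Without WT arrays 7, 8 and 9 there were 1 gene at 5 weeks, 4 in the average, 991 and 851 in the age comparisons and 0 in the interaction of 5 with 2 weeks. The actin covariate gave 780 for WT 44 against 5 weeks, and the Gapdh covariate 1660 at 5 weeks, 1089 in the average, 2572 for WT 5 against 2 weeks and 0 in the interaction of 5 with 2 weeks. The sex covariate gave 1 gene at 44 weeks and 421 in the average. At 44 weeks 7 genes were called with no filter and 0 with the lower 50% left out. The interaction of 5 with 2 weeks had 1 gene after quantile normalization, with arrays centred and with a trended robust prior. All other alternatives for these counts, leaving out single arrays apart, stayed within 1.5 times.

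Of gene lists, the estimated correlation called 0 in each of the 6 comparisons, and fry called 0 at 2 and at 44 weeks. At 5 weeks fry called the injury and oxidative phosphorylation lists (adjusted p = 0.006 each) and the endothelium, loop and distal and leukocyte lists (0.023 each). It also called the proximal tubule and ribosomal lists (0.028 each). The slit diaphragm (fry adjusted p = 0.07), podocyte identity (0.24) and immediate-early lists (0.12), called by camera, were not called by fry. The tubule covariate left 4 lists at 2 weeks, 2 at 5 weeks, 4 at 44 weeks and 4 in the average, and without WT arrays 7, 8 and 9 there were 5 at 5 weeks. The correlations of fold changes between ages became -0.013, 0.00622 and 0.0509 with the tubule covariate. The odds ratios near Actn4 kept their side with windows of 10 and 40 Mb.

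Leaving out single arrays gave 0 to 1 genes at 2 weeks (1 without KI 2-week 20 or KI 44-week 34). At 5 weeks it gave 1386 to 4077: 1386 without WT array 7, 1483 without WT 9, 4077 without WT 10 and 1480 without KI 23. At 44 weeks it gave 1 to 45: 45 without WT array 15 and 1 without WT 17 or KI 31. The average ranged from 101 to 1828. It was 365 and 160 without WT 2-week arrays 1 and 2, 297, 353, 238 and 1789 without WT 5-week arrays 7, 8, 9 and 10, and 1828, 121, 151 and 214 without WT 44-week arrays 15, 16, 17 and 18. It was 311, 272 and 101 without KI 2-week arrays 19, 21 and 22, 226, 342 and 227 without KI 5-week arrays 23, 24 and 26, and 278, 403 and 215 without KI 44-week arrays 31, 32 and 33. WT 5 against 2 weeks ranged from 3178 to 4757 and 44 against 5 weeks from 1629 to 3103.

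The interaction of 5 with 2 weeks ranged from 0 to 1521 genes. It had 1521 without WT 5-week array 10, 0 without KI 2-week 19 or 21 or KI 5-week 25 or 26, and 1 without WT 2-week 1, 3 or 5, WT 5-week 6, 7, 8 or 9, WT 44-week 18, KI 2-week 20 or 22, KI 5-week 23 or KI 44-week 32. That of 44 with 5 weeks ranged from 0 to 1561 (1561 without WT 5-week 10, 2 without WT 44-week 17), and that of 44 with 2 weeks from 0 to 1 (1 without KI 44-week 33). Lists called ranged from 5 to 8 at 2 weeks, 8 to 11 at 5 weeks, 4 to 8 at 44 weeks (4 without WT 44-week 16 or KI 44-week 33), 8 to 10 in the average, 7 to 10 for WT 5 against 2 weeks and 9 to 13 for 44 against 5 weeks.

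Of 365 named values, 355 kept direction and call after quantile normalization, 357 with arrays centred, 335 with the sex covariate, 182 with the tubule covariate and 147 without WT arrays 7, 8 and 9. With the tubule covariate Myo7a (-0.01), Cgn (-0.01), Lcp1 (-0.34) and Slc4a1 (-0.09) reversed at 5 weeks, Myh10 (-0.09) and Myh11 (-0.25) in the average, and Krt18 (-0.39) for WT 44 against 5 weeks. Without WT arrays 7, 8 and 9 Col1a1 (-0.09) reversed at 5 weeks. With all probe sets averaged, Psmd9 (-0.22) reversed at 5 weeks, Xaf1 (-0.43) for WT 5 against 2 weeks, and Prkci (0.07) and Podxl (0.20) for WT 44 against 5 weeks. Signal over background limits dim genes: those with a mean under 4.603 were not tested.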

Other observations

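The myosin group and the values per array below were chosen after the data were seen. Of 21 myosin heavy chain genes tested, 20 had higher means in KI at 2 weeks, 19 at 5 weeks and 20 at 44 weeks, with median log2 fold changes of 0.83, 1.47 and 0.67, and 15 passed at 5 weeks. Without WT 5-week arrays 7, 8 and 9 the 5-week median was 0.667 and none passed, and with array weights the medians were 0.55, 1.684 and 1.122. In the average over ages 13 passed in limma (median 0.98), among them the non-muscle myosins Myh9 (1.16) and Myh10 (1.53), the vesicle motor Myo5b (1.40), Myo18a (1.14), the mitochondrial Myo19 (0.98) and the filopodial Myo10 (0.49). No test of the group is given, since its members were seen among the largest rises, and with the tubule covariate 1.63% of the median fold over ages was kept. In WT the same genes had medians of 0.11 from 2 to 5 weeks and 0.18 from 5 to 44 weeks.

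Array values are given without explanation. WT 5-week array 10, whose absence raised the counts most at 5 weeks, had Gm38983 at 4.62, Dmpk at 4.39, Prodh2 at 6.88 and Eml2 at 11.78, on the side of the other WT arrays for each. KI 44-week array 34 had Gm38983 at 6.44, Prodh2 at 7.99, Dmpk at 4.05 and Eml2 at 11.32. The most similar pair of arrays was WT 2-week 3 and 5 (SD of the difference 0.263, r = 0.99473), so no array was a copy of another.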
